A study of Drosophila melanogaster with 8 samples.

How the data were processed

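The series held 8 spotted arrays of Drosophila melanogaster, each with larval RNA in one channel and adult RNA in the other. Both came from the wild-type strain Canton S and both were mixtures of stages. Per the labels, the samples were portions of one master homogenate in TRIzol, a phenol-based reagent for RNA extraction, and each portion was processed on its own. All 8 arrays are therefore technical replicates, and p-values measure only the technical spread between arrays, not the spread between animals or cultures. Per the labels' descriptions, polyA RNA was selected on oligo-dT cellulose and labelled by the amino-allyl method, while GEO's molecule field names total RNA. Per the labels, arrays were scanned with GenePix on an Axon 4000 series scanner and spots were quantified with Spot version 2.0. The dyes, the background handling, spot filters and the channel used as numerator are not given in the sources used here.

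The deposited value of each spot was a log2 ratio of the 2 channels. The unit was read from the values: all 20000 spots of each of the 8 arrays were the log2 of a ratio of 2 whole numbers no larger than 58096, within a relative tolerance of 1e-13. In 300 sampled spots per array, at most 1.67% met the same criterion with base 10 and at most 1.33% with base e. On 5000 simulated spots the search recovered 100% of the ratios. No value was missing. The deposited values showed no centring: array medians were -0.09, 0.12, -0.69, -0.11, 0.13, -0.26, 0.51 and -0.70 for replicates 1 to 8. A brightness was computed for each spot as the mean log2 of the recovered whole numbers, taking the median over arrays, and it is a lower bound because common factors are lost. No signal or background level was used here, and the number of arrays limits the precision.

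Replicates 1, 3, 6 and 8 had larvae in channel 1 and replicates 2, 4, 5 and 7 had adults in channel 1. As deposited, arrays of opposite orientation correlated negatively over spots, with Pearson's r from -0.81 to -0.51, so the values had not been turned to one stage. Here the sign was reversed on the arrays with adults in channel 1, which gives the turned ratio. A positive turned ratio stands for more larval RNA if channel 1 was the numerator and for more adult RNA if channel 2 was. The sources used here do not settle this, so results are given by side, positive or negative, with no stage attached.

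Spots were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with a stage column and a dye column, arrays centred on the median of all spots, and Benjamini-Hochberg adjustment at 0.05. Genes were fitted in the same way on the mean of a gene's spots, with arrays centred on the median of genes. That centring of the gene fit was chosen after seeing the data, and centring on all spots was run beside it. The technical error is the residual SD of these fits, with 6 residual degrees of freedom. Subsets of 4 and of 6 arrays with equal orientations were fitted again. Gene lists were tested with camera at a preset correlation of 0.01, which compares a list with the other genes, and with an estimated correlation as an alternative. They were also tested with fry, which asks whether a list's genes move one way on balance and compares them with no other genes. Recovery and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

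The probe table paired 12246 spots with 1 gene and 86 with several, and 7668 spots were unnamed here. Of the spots with 1 gene, 11771 matched a current gene through the RefSeq gene table of Release 6, used for names alone, and 475 kept the probe table's symbol. No gene was named from a spot with several genes. This gave 10658 genes, 1231 of them with at least 2 spots. Of 435 genes with at least 2 spots past the threshold, 77 had such spots on opposite sides, and 0 of these are named in the text. Whether probes tell close gene copies apart is not given in the sources used here, so values of the Jonah proteases, trypsins, lysozymes, cuticle proteins and other multigene families are uncertain for single members.

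Before the data were examined, 29 gene lists were written, along with the tests, the alternatives and the rule for named genes. The rule takes the 12 genes with the largest mean ratio on each side among those past the threshold with one sign on all 8 arrays, and up to 4 members of each list with the largest absolute ratio. A further set of genes (aly, can, comr, achi, topi, twe, bol, ProtA, ProtB, dj, Hsp60B, TrxT and Mal-A7) is named outside that rule and was chosen after their values were seen. Members of lists given as name stems were taken from the gene table, with cyclophilins left out of the cytochrome P450 stem, a choice made after seeing the data. 7 genes stood in more than 1 list.

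The fits were tested on simulated data with the real genes and spreads and 200 changed features. In the simulated stage difference of 10658 genes, 83.6% of the genes shifted by 0.5 (log2) were recovered and 100% of those shifted by 1 or 2, with 15 false calls, 7.35% of the calls. In that of 20000 spots, 31.3% of the spots shifted by 0.5 were recovered and 100% of the larger shifts, with 9 false calls, 5.52% of the calls. These rates are for 200 changed features, while 6077 genes passed on the real arrays. There the first component of the genes' residuals held 57.2%, so errors were shared between genes. The rates therefore do not measure recovery or false calls on the real arrays. In a simulated shift of the proteasome list by 0.5, camera recovered that list and called 0 others. That 0 does not measure false list calls on the real arrays. There the estimated correlation within a list reached 0.922 (glycolysis), and splits of the arrays that kept none of the stage difference gave up to 16 lists. Alternatives covered centring, scaling, quantile normalization, the dye term, robust variance moderation, array weights, dim spots, the choice of probe and each replicate left out. Alternatives added after seeing the data were spots paired with a gene, a loess curve against brightness (span 0.3) and, for genes, centring on all spots.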

Results

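Each of the 8 arrays compared RNA of larvae with RNA of adults of Canton S, a wild-type strain of Drosophila melanogaster, over 20000 spots. Larvae were in channel 1 on 4 arrays and in channel 2 on 4. The labels give the purpose as an assessment of technical error. Ratios below are turned log2 ratios, and the side that stands for larvae is not settled by the sources used here. Errors are SDs over the 8 arrays (n = 8) unless stated.

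The first comparison asked which genes differed between the larval and the adult RNA. On the positive side the largest ratios belonged to cuticle protein genes and to genes of mixed function. Cpr72Ea reached 4.93 ± 0.66, Cpr97Eb 4.86 ± 0.28, Cpr64Ac 4.23 ± 0.29, Cpr49Ah 3.92 ± 0.46 and Cpr49Ae 3.63 ± 0.23. Fbp1, a fat body receptor for larval serum proteins, was at 4.30 ± 0.29, the serpin gene Spn43Aa at 4.25 ± 0.37, the troponin C gene TpnC4 at 3.87 ± 0.50 and Mst98Cb, a sperm tail gene, at 3.54 ± 0.36. CG13023 had the largest ratio of the named genes, 5.17 ± 0.58, and CG1850 and CG4151 stood at 4.78 ± 0.33 and 4.29 ± 0.27.

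On the negative side, 6 of the 12 largest ratios belonged to genes of the digestive list. The Jonah serine protease genes Jon25Bi, Jon99Fii, Jon25Bii and Jon25Biii stood at -4.22 ± 0.82, -4.07 ± 0.75, -4.02 ± 0.72 and -3.87 ± 0.77. The trypsin gene betaTry was at -3.49 ± 0.88 and the lysozyme gene LysE at -3.41 ± 0.92. The others were w-cup (-3.80 ± 0.84), CG18180 (-3.60 ± 0.70), CG14143 (-3.58 ± 0.76), CG15225 (-3.51 ± 0.87), CG6296 (-3.48 ± 0.83) and CG13705 (-3.47 ± 0.82). The rule that chose these 24 genes required the threshold and one sign on all 8 arrays, so neither is a separate result. The highest limma adjusted p among them was 8.77e-07, for betaTry.

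**Figure D1:**
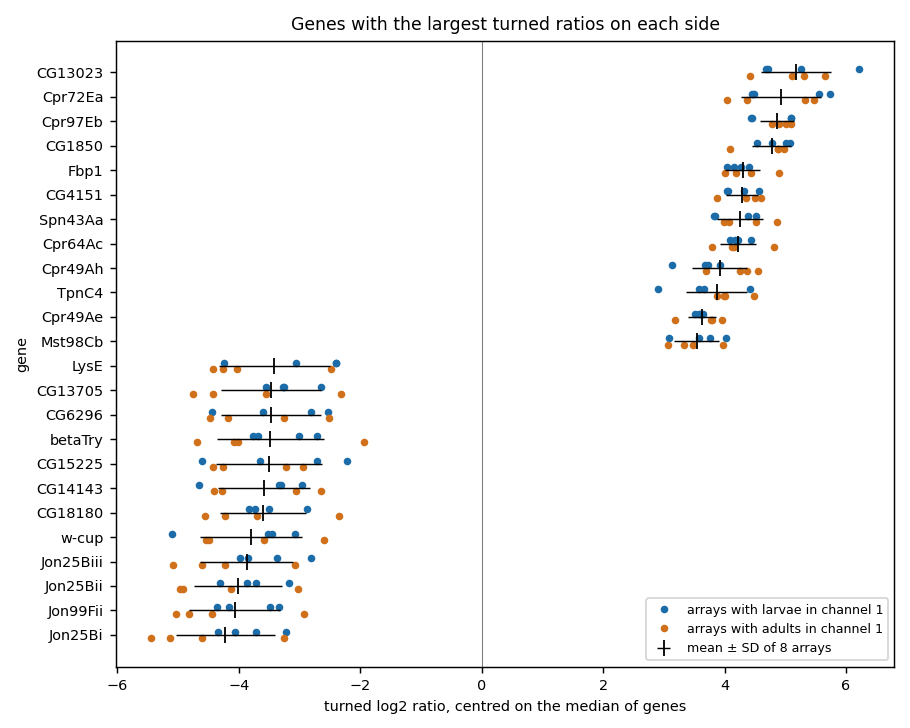
Turned log2 ratio (horizontal axis) of the 12 named genes with the largest ratios on each side (vertical axis); points are single arrays, coloured by the stage in channel 1, and bars are the mean ± SD of 8 arrays. The means run from 3.54 to 5.17 on the positive side and from -4.22 to -3.41 on the negative side.

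In the limma fit of genes, 6077 of 10658 genes (57.0%) passed an adjusted p of 0.05, 3135 on the positive and 2942 on the negative side, and 674 and 328 of these differed at least 2-fold. With arrays centred on all spots the split was 2059 positive and 3707 negative of 5766, and with values as deposited 1040 and 6059 of 7099, where the median of all genes moved to -0.15 and -0.45. In the fit of all spots, 8491 of 20000 passed (42.5%), 4117 positive and 4374 negative, against 1756 and 7302 of 9058 as deposited. The spot count was 13120 without replicate 3 and 13696 with array weights.

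The digestive list, proteases and glycosidases of the gut, had 32 of 33 measured genes past the threshold on the negative side and 0 on the positive, with a median of -2.76. Mal-A7, named after its value was seen, was the member not past it, at -0.17 ± 0.45, and it passed as deposited (adjusted p = 0.00336) and centred on all spots (0.0464). Its brightness was low, at percentile 5.83 of genes, but dimmer members of the list passed. The camera adjusted p was 4.03e-17, and adjusted p = 0.420 with an estimated correlation. Salivary glue proteins, which fix the pupal case to its support, had 5 of 7 genes on the negative side and 2 not past the threshold, with a median of -1.44. Sgs1 was at -2.38 ± 0.76, Eig71Ee at -2.03 ± 0.71, ng3 at -1.58 ± 0.68 and Sgs5 at -1.44 ± 0.60. Camera gave an adjusted p of 0.00641, and adjusted p = 0.420 with an estimated correlation.

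Larval cuticle proteins went both ways, with 19 of 27 genes on the negative and 8 on the positive side and a median of -0.91. As deposited 19 were negative and 5 positive, with a median of -1.35. Lcp9 stood at -2.74 ± 0.68, against 3.92 for Cpr49Ah, 3.63 for Cpr49Ae and 2.80 ± 0.62 for TwdlT. The camera adjusted p was 0.0111 on the negative side, adjusted p = 0.528 with an estimated correlation, and fry, which compares a list with no change and not with other genes, gave 0.310. Pupal and adult cuticle proteins had 6 of 10 genes on the positive side, 1 on the negative and 3 not past the threshold, with a median of 0.78. As deposited 5 were positive and 3 negative, with a median of 0.34. Edg78E was at 3.07 ± 0.28, Acp65Aa at 2.22 ± 0.60, Pcp at 2.14 ± 0.38 and Edg84A at 2.04 ± 0.35. Camera gave 0.0166, adjusted p = 0.420 with an estimated correlation, and 0.0777 with arrays scaled to one spread. Of the larval serum protein list, 2 genes were measured and no list test was run: Fbp1 at 4.30 and Fbp2 at -0.35 ± 0.97, the latter not past the threshold (-0.66, adjusted p = 0.00500 without replicate 7, and -0.79, adjusted p = 0.00271 as deposited).

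Genes of the response to ecdysone, the moulting hormone, had 19 of 25 members on the positive side, 1 on the negative and 5 not past the threshold, with a median of 0.55. As deposited 8 were on the positive and 6 on the negative side, with a median of 0.11, and centred on all spots 14 and 3. ImpE2 was at 2.88 ± 0.41, Eig71Ea at 2.44 ± 0.65, Eig71Ed at 2.36 ± 0.29 and Eig71Eg at 2.22 ± 0.50. The camera adjusted p was 5.78e-05, and adjusted p = 0.420 with an estimated correlation. In the chitin and peritrophic matrix list, 14 of 27 genes were on the positive and 8 on the negative side, with a median of 0.38, against 9 and 11 and a median of -0.06 as deposited. The chitinase genes Cht5 and Cht10 stood at 3.22 ± 0.56 and 1.89 ± 0.28, and Peritrophin-15a and Peritrophin-15b, of the gut lining, at -2.36 ± 0.62 and -1.61 ± 0.37. That list did not pass camera (adjusted p = 0.200).

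Testis and sperm genes had 18 of 31 members on the positive side, 4 on the negative (5 adjusted over the list alone, 2 without replicate 3) and 9 not past the threshold, with a median of 0.77. As deposited 15 were positive and 10 negative, with a median of 0.33. Mst98Cb stood at 3.54, Mst77F at 2.96 ± 0.43, S-Lap8 at 2.20 ± 0.44 and S-Lap2 at 2.20 ± 0.58. Camera gave an adjusted p of 0.00182, and adjusted p = 0.420 with an estimated correlation. Eggshell proteins had 8 of 13 genes on the negative side and 0 on the positive, with a median of -0.34, and as deposited 13 of 13 were on the negative side. The members with the largest ratios were psd (-0.76 ± 0.46), ndl (-0.66 ± 0.47), Vm26Ac (-0.63 ± 0.31) and yellow-g2 (-0.57 ± 0.28). Camera gave 0.00794, and adjusted p = 0.420 with an estimated correlation.

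The yolk protein genes Yp1 and Yp2 were on the positive side at 1.17 ± 0.40 and 0.75 ± 0.28, and Yp3 at 0.03 ± 0.11 was not past the threshold. As deposited, Yp3 was at -0.41 with an adjusted p of 0.0195 and Yp2 at 0.32 with 0.0610. The list did not pass camera (adjusted p = 0.142). The list of male accessory gland proteins was split, 5 positive and 6 negative of 18 and 2 and 12 as deposited (camera adjusted p = 0.536). EbpIII, an ejaculatory bulb protein gene in that list, was at 1.52 ± 0.42 and Mst89B at 0.82 ± 0.24. Acp29AB stood at -0.59 ± 0.43 and Acp76A at -0.55 ± 0.43. The members named Acp ran from -0.59 to 0.50. Oogenesis and maternal genes had 4 positive and 6 negative of 24, 4 and 15 as deposited, and 3 negative without replicate 8. Their median was -0.06 (-0.01 without replicate 7) while their mean was 0.17 and camera's side positive (adjusted p = 0.891), with exu at 2.52 ± 0.39, stau at 1.41 ± 0.28, orb at 1.25 ± 0.40 and tud at 0.81 ± 0.23.

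Flight muscle genes had 11 of 21 members on the positive side (12 adjusted over the list alone), 1 on the negative and 9 not past the threshold, with a median of 0.42. As deposited 6 were positive and 3 negative, with a median of -0.02, and without replicate 7 the median was 0.26. Besides TpnC4 at 3.87, fln (flightin) stood at 2.35 ± 0.68, TpnC41C at 1.94 ± 0.46 and Act88F, the flight muscle actin, at 1.64 ± 0.80. Camera gave 0.00577, adjusted p = 0.534 with an estimated correlation and 0.0606 after a loess curve against brightness, an alternative chosen after seeing the data. Of 5 larval and embryonic muscle genes, betaTub60D (1.47 ± 0.81) and Act87E (0.76 ± 0.82) were on the positive side, and Mp20 (-0.56 ± 0.76) and Mf (-0.50 ± 0.47) on the negative. Act87E was not past the threshold as deposited (adjusted p = 0.103). Mp20 passed it at 0.0474 and not without replicate 1, 2, 3, 4, 5, 6 or 8, at 0.0564 to 0.122. The list's median of 0.12 was -0.31 as deposited, -0.02 centred on all spots and -0.01 after the loess curve, and camera gave 0.724.

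Phototransduction genes had 9 of 19 members on the positive side and 1 on the negative, with a median of 0.10 that was -0.04 centred on all spots, 0.16 without replicate 7, 0.15 without replicate 2 and 0.06 without replicate 4. As deposited 4 were positive and 7 negative, with a median of -0.34. Pdh was at 2.17 ± 0.50, chp (chaoptin) at 1.34 ± 0.41, trp, an ion channel gene, at 1.06 ± 0.37 and Ggamma30A at 0.89 ± 0.28. Neuronal genes had 8 of 24 on the positive side and 1 on the negative, with a median of 0.14. As deposited 4 were positive and 9 negative, with a median of -0.30. Centred on all spots 6 were positive and 2 negative, with a median of 0.0008. They included ple, the tyrosine hydroxylase gene, at 1.89 ± 0.33, Nrg at 1.41 ± 0.43, nrv3 at 1.01 ± 0.44 and elav at 0.81 ± 0.34. The camera adjusted p values of the phototransduction and neuronal lists were 0.0652 and 0.0526, adjusted p = 0.495 and 0.420 with an estimated correlation. Without replicate 7 they were 0.0368 and 0.0259, and the neuronal list also passed under scaling (0.0401), after the loess curve (0.0456) and without replicate 6 (0.0473). Odorant-binding and chemosensory genes had 3 positive and 9 negative of 23 (camera adjusted p = 0.148), and 2 and 18 as deposited. The negative count was 14 without replicate 7 and 6 without replicate 2, 3, 6 or 8. Obp99c was at 2.34 ± 0.43, Obp56a at 1.30 ± 0.68, Obp56b at -0.58 ± 0.28 and Obp99b, not past the threshold, at -0.56 ± 0.95. Obp99b passed it without replicate 1 (adjusted p = 0.0349), without replicate 7 (0.000620), centred on all spots (0.00987) and as deposited (0.000860).

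Cytochrome P450 genes, oxidases of hormone and toxin metabolism, had 52 of 79 members on the negative side, 10 on the positive and 17 not past the threshold, with a median of -0.35. As deposited 64 were negative and 2 positive, with a median of -0.79. Cyp12a4 was at -1.59 ± 0.48 and Cyp12a5 at -1.41 ± 0.61, against Cyp4g1, a gene of cuticular hydrocarbon synthesis, at 2.37 ± 0.52 and Cyp9c1 at 1.60 ± 0.82. Camera gave 4.71e-05, and adjusted p = 0.420 with an estimated correlation. Glutathione S-transferase genes had 12 negative and 7 positive of 27 (adjusted p = 0.289) and 17 and 0 as deposited, with GstD7 at -1.28 ± 0.72, GstD10 at -0.80 ± 0.73, GstE10 at -0.75 ± 0.24 and GstD2 at -0.74 ± 0.83. GstD2 did not pass without replicate 1 (adjusted p = 0.0561) or 4 (0.0543). Lipid storage genes had 8 negative and 3 positive of 17, and 13 and 0 as deposited. Their camera adjusted p was 0.0609, 0.0299 without replicate 7, 0.0383 after the loess curve and 0.0319 with the probe of smallest residual SD, and adjusted p = 0.420 with an estimated correlation. The fatty acid synthase gene FASN1 was at -2.45 ± 0.59, Desat1 at -1.19 ± 0.50 and ACC at -0.92 ± 0.52, and Lsd-2 stood at 0.75 ± 0.58 (0.31 as deposited, adjusted p = 0.0651).

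Proteasome genes had 25 of 39 members on the positive side, 1 on the negative and 13 not past the threshold, with a median of 0.49. As deposited 5 were on the positive and 11 on the negative side, with a median of 0.05, and after the loess curve 21 and 3, with a median of 0.26. Rpn12R was at 0.94 ± 0.37, Prosbeta2 at 0.88 ± 0.64 and Prosbeta5R1 at 0.86 ± 0.35. Prosalpha6T, which also stood in the testis list, was at -2.15 ± 0.70. No difference between testis copies and other subunits was tested. Camera gave 0.00700, and adjusted p = 0.521 with an estimated correlation. Heat shock and chaperone genes had 7 of 11 on the positive side and 1 on the negative, with a median of 0.55. As deposited 3 were positive and 2 negative, with a median of 0.11. Hsp27 was at 2.62 ± 0.44, Hsp26 at 2.36 ± 0.34 and Hsp68 at 1.196 ± 0.48, and Hsp60A at -0.67 ± 0.42. Camera gave 0.0195, adjusted p = 0.495 with an estimated correlation and 0.0780 after the loess curve. Antimicrobial and immune recognition genes had 6 positive and 2 negative of 12 (adjusted p = 0.166), with a median of 0.28. As deposited 3 were positive and 5 negative, with a median of -0.16, and 4 were negative without replicate 7 and 1 without replicate 3 or 6. Drs (drosomycin) was at 2.60 ± 0.50, AttB at 1.02 ± 0.39, Mtk at 0.92 ± 0.33 and PGRP-SC2 at -0.84 ± 0.74.

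Glycolysis genes had 2 of 10 members on the negative side (1 adjusted over the list alone), 1 on the positive and 7 not past the threshold, with a median of -0.43, and as deposited 8 were negative and 0 positive. Hex-C was at -0.63 ± 0.40 and Eno, the enolase gene, at -0.68 ± 0.94 with an adjusted p of 0.0457, which was 0.0504 to 0.124 without replicate 1, 2, 3, 4, 5, 6 or 8. Tpi (-0.60 ± 0.90) and Gapdh1 (-0.57 ± 0.90) were not past the threshold. They passed it as deposited (adjusted p = 0.000324 and 0.000351), centred on all spots (0.00991 and 0.0104), under scaling (0.0418 and 0.0431) and under quantile normalization (0.0348 and 0.0369). Without replicate 7 they stood at -0.88 and -0.85 with adjusted p values of 0.000633 and 0.000648. The list had 8 negative genes without replicate 7 (median -0.70), 6 under scaling and under quantile normalization, 1 with any other replicate left out, and 0 positive without replicate 3 or 8. Its camera adjusted p went from 0.267 to 0.0172 without replicate 7, and was 0.857 with an estimated correlation. Cytosolic ribosomal protein genes had 4 positive and 1 negative of 34 (adjusted p = 0.148), with a median of 0.28. As deposited 2 were positive and 9 negative (median -0.16), after the loess curve 3 and 9 (median 0.03), and without replicate 7 there were 6 and 4 (median 0.10). Under scaling and under quantile normalization 6 were positive (medians 0.16 and 0.19), and 9 were without replicate 1 (median 0.43) or 4, while 2 were negative without replicate 3 or 6. RpL40 was at 1.04 ± 0.81, RpL10Aa at 0.99 ± 0.45, RpL24-like at 0.64 ± 0.61 (0.20 as deposited, adjusted p = 0.255) and RpS18, not past the threshold, at 0.58 ± 1.00.

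Mitochondrial ribosomal protein genes had 13 negative and 3 positive of 61 (11 and 0 adjusted over the list alone), and as deposited 48 negative and 0 positive. The positive count was 5 without replicate 1, 1 without replicate 2, 3, 5 or 6 and 0 without replicate 8. The members with the largest ratios were mRpS7 (-0.75 ± 0.33), mRpL44 (-0.63 ± 0.37), mRpL42 (0.49 ± 0.54) and, not past the threshold, mRpL4 (0.44 ± 0.70). mRpL42 did not pass without replicate 2, 6 or 8 (adjusted p = 0.0523, 0.0629 and 0.0688) or as deposited (0.747), and mRpL4 passed without replicate 1 (0.0276). The brightness of mRpL42 was low, at percentile 0.704 of genes. The list's camera adjusted p was 0.148, 0.0226 without replicate 7, 0.0417 under scaling, and adjusted p = 0.857 with an estimated correlation. Oxidative phosphorylation genes had 8 positive and 4 negative of 63 (3 and 4 adjusted over the list alone; camera adjusted p = 0.472), against 2 and 33 as deposited, 3 and 5 centred on all spots, 5 and 11 after the loess curve, 7 and 8 without replicate 7, 3 and 4 without replicate 3 and 5 and 4 without replicate 5 or 8. Their median of 0.09 was -0.35 as deposited, -0.05 centred on all spots, -0.02 under scaling, 0.0041 under quantile normalization, -0.03 after the loess curve, -0.07 without replicate 7, 0.16 without replicate 1 or 4, 0.14 without replicate 5 and 0.04 without replicate 8. COX4L was at 2.07 ± 0.29, COX7AL at 1.23 ± 0.52, ATPsynepsilonL at -2.30 ± 0.60 and COX6AL2 at -0.70 ± 0.28.

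Genes of the tricarboxylic acid cycle had 5 positive and 2 negative of 14 (adjusted p = 0.416) and 3 and 6 as deposited, and 3 were positive without replicate 3 or 8. Their median of 0.20 was -0.24 as deposited, -0.10 after the loess curve, 0.11 under scaling, 0.12 under quantile normalization and 0.08 without replicate 7. Centred on all spots it was 0.06, with 3 genes positive and 2 negative. Idh3b was at 1.13 ± 0.65, Idh3g at 1.09 ± 0.46, ScsbetaA at 0.85 ± 0.49 and PCB, pyruvate carboxylase, at -0.80 ± 0.59. DNA replication and cell cycle genes had 7 positive and 6 negative of 31 (adjusted p = 0.819), against 0 and 17 as deposited and 4 and 8 centred on all spots, with a median of 0.02 that was -0.42 as deposited, -0.12 centred on all spots, -0.01 under scaling or quantile normalization and -0.0042 after the loess curve, and ran from 0.0037 to 0.05 with one replicate left out. Orc5 was at 0.79 ± 0.35, RPA1 at 0.71 ± 0.34, CycB at 0.66 ± 0.18 and RnrL at 0.54 ± 0.51, and none of these 4 passed the threshold as deposited.

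**Figure D2:**
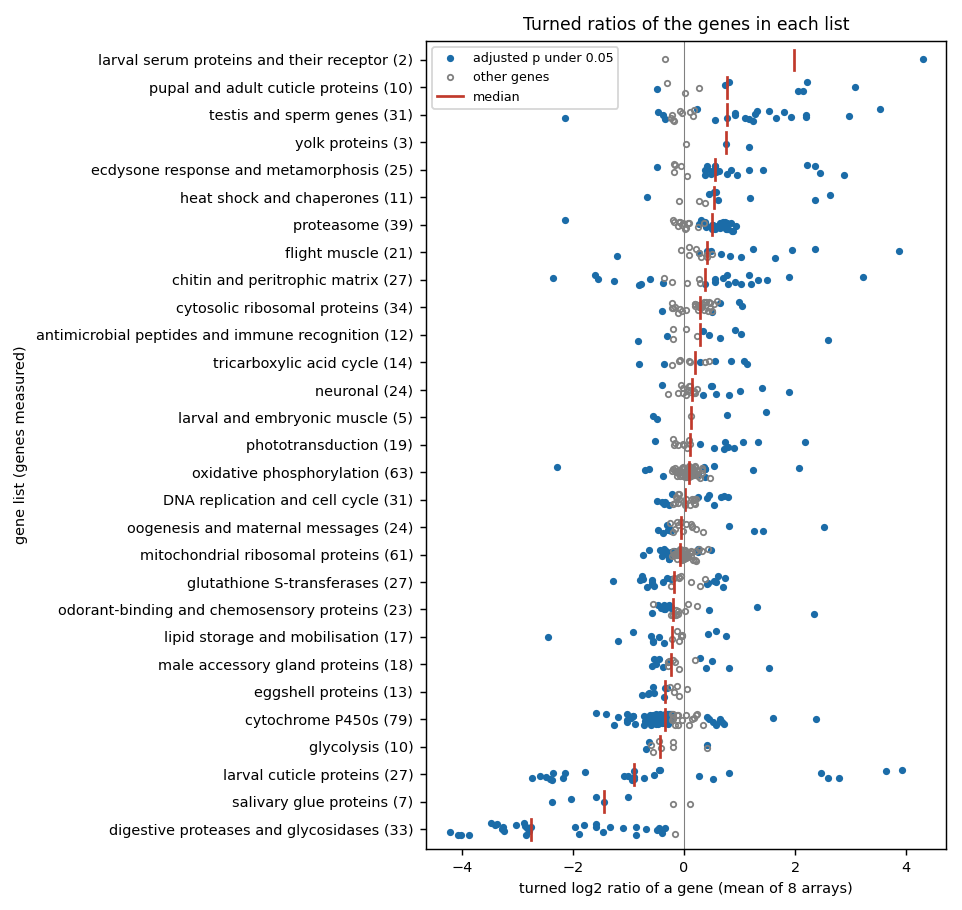
Turned log2 ratio of each gene (horizontal axis, mean of 8 arrays) by gene list (vertical axis, with the number of genes measured); filled points passed an adjusted p of 0.05 and red bars are list medians. Digestive enzymes have the lowest median, -2.76.

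Of the 28 lists tested, 11 passed camera at the preset correlation, 6 on the positive and 5 on the negative side, and 0 passed with an estimated correlation. Relative to the median of all genes, 2 of the 28 list medians changed sign under scaling, 2 without replicate 7, and 1 each under quantile normalization and the loess curve. Counts adjusted over the list alone equalled those over all genes in the lists where no second count is given.

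The second comparison asked how precise the arrays were. The spread between arrays differed between gene groups. The median residual SD was 0.760 for cytosolic ribosomal protein genes, 0.812 for glycolysis, 0.663 for digestive enzymes and 0.633 for flight muscle, against 0.256 for DNA replication and 0.257 for oogenesis genes. Over all genes it was 0.301 (quartiles 0.221 and 0.402), and over all spots 0.421 (quartiles 0.323 and 0.520). For a gene at the median, the 95% half-width was 0.260 for a mean of 8 arrays, 0.368 for 4 and 0.520 for 2, or 1.198-, 1.29- and 1.43-fold. For a spot at the median it was 0.364, 0.515 and 0.729. The half-widths for 4 and 2 arrays kept the residual SD and the degrees of freedom of the 8-array fit. An experiment with only 4 or 2 arrays would have fewer degrees of freedom, and no half-width was computed for one.

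Across genes, which are not independent replicates, turned arrays of one orientation correlated with Pearson's r from 0.592 to 0.947 (median 0.819, 12 pairs) and those of opposite orientation from 0.561 to 0.877 (median 0.816, 16 pairs). The array of replicate 7 stood apart: its r with the mean of the other arrays was 0.750, against 0.851 to 0.915 for the rest. Without it the ribosomal protein genes had a median residual SD of 0.393 and all genes 0.237, and 6278 genes passed the threshold.

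Fits on 4 arrays called a median of 3888.5 genes over 36 subsets, from 1828 to 6304, and a median of 73.4% of these, from 32.2% to 98.8%, were called on the same side by the arrays left out. At most 2 genes per subset were called on opposite sides. Fits on 6 arrays called a median of 4964.5 genes over 16 subsets, from 4498 to 6667. For spots, the 4-array fits called a median of 3996.5, from 2398 to 12743, and a median of 74.1%, from 19.96% to 98.1%, were called on the same side by the arrays left out, with at most 14 on opposite sides.

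The third comparison asked which genes followed the channel and not the stage. In the limma fit, 0 of 10658 genes and 0 of 20000 spots passed the threshold for the dye column, and 484 genes (4.54%) and 448 spots (2.24%) had an unadjusted p under 0.05. Without replicate 7 this unadjusted count was 1559 genes, and without replicate 5 it was 259. For spots it was 2548 without replicate 3 and 157 without replicate 5. Centring the arrays removes any dye offset shared by most spots, so the dye column does not measure such an offset. Of the named genes, those with the largest dye terms, a choice made after seeing the data, were Obp99b (0.42), LysE (0.39), Jon25Bi (0.39) and Jon25Biii (0.37), each with a limma adjusted p of 0.912. With array weights, 1213 genes and 2113 spots passed.

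Spots that the probe table does not list differed in brightness from those with a gene. Of the 5000 spots in the dimmest 25%, 14 were paired with a gene. In the fit centred on all spots, 960 of these 5000 passed the threshold, 958 of them on the positive side, and 0 differed at least 2-fold. Of the 15000 brighter spots, 7531 passed, 3159 positive and 4372 negative. With arrays centred on all spots, the median was below 0 for spots paired with a gene and above 0 for the dimmest 25% on 6 of the 8 arrays. On replicates 3 and 5 it was 0.24 and 0.03 for spots paired with a gene, and -0.27 and -0.06 for the dimmest 25%.

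**Figure D3:**
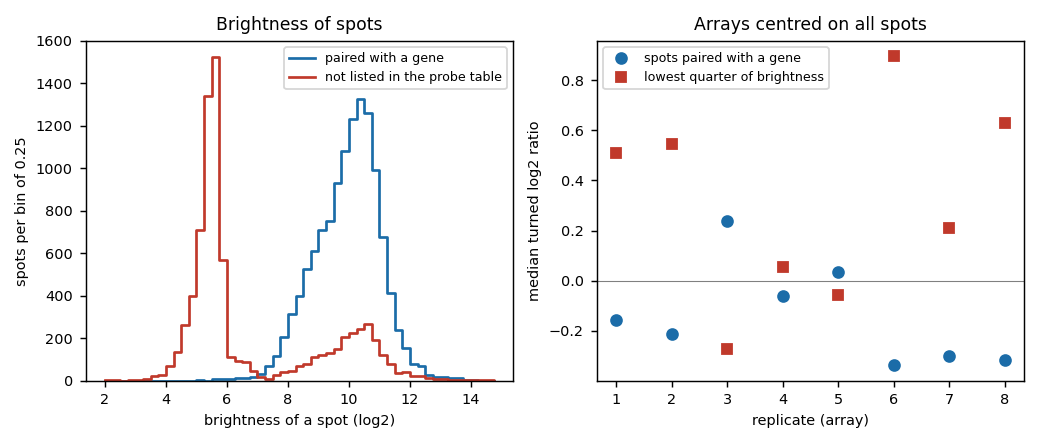
Left: number of spots (vertical axis) by brightness (log2, horizontal axis) for spots paired with a gene and spots not listed in the probe table. Right: median turned log2 ratio per array (horizontal axis, replicate) of spots paired with a gene and of the dimmest 25% of spots, with arrays centred on all spots; the means of these medians over arrays were -0.14 and 0.31, and replicates 3 and 5 had the opposite signs.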

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

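Single arrays far from the other 3 of their orientation are given here. Of 288 groups of 4 values tested, 29 held such an array, where chance gives about 14.4 (1 in 20), and 18 of the 29 were replicate 7 and 7 were replicate 3. The test of replicate 7 below was written when that array had already been seen to stand apart, and the bootstrap spread of both ratios was added after the ratios were seen.

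On replicate 7, with the range of the other arrays with adults in channel 1, Fbp2 was at 1.34 (-1.29 to -0.94), TwdlT at 3.61 (2.10 to 2.23) and Acp76A at -1.48 (-0.38 to -0.20). Obp56a was at 2.77 (0.86 to 1.08) and Obp99b at 0.67 (-1.73 to -1.35). The muscle genes Act88F, Act87E and Mf were at 2.71 (0.77 to 0.92), 2.15 (-0.08 to 0.04) and 0.48 (-0.92 to -0.71). The metabolic genes Tpi, Idh3b, ScsbetaA and PCB were at 0.82 (-1.48 to -1.25), 2.16 (0.29 to 0.61), 1.76 (0.38 to 0.52) and 0.23 (-1.51 to -1.27). The ribosomal protein genes RpL24-like and RpS18 were at 2.00 (0.23 to 0.47) and 2.73 (-0.21 to 0.27), and mRpL44 and mRpL4 at -1.30 (-0.43 to -0.31) and 1.40 (-0.23 to -0.19). The testis genes aly and can, named after their values were seen, were at -1.004 (-0.35 to -0.23) and -1.09 (-0.13 to 0.01).

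On replicate 3, with the range of the other arrays with larvae in channel 1, Acp65Aa was at 3.05 (1.54 to 1.79), Eig71Eg at 2.99 (1.67 to 1.83), Yp3 at -0.22 (0.01 to 0.05) and Mst77F at 3.80 (2.48 to 2.60). TpnC41C was at 2.63 (1.37 to 1.58), Cht5 at 3.96 (2.77 to 2.92) and TrxT at 2.02 (0.71 to 0.87). On replicate 2, CG1850 was at 4.09 (4.87 to 4.98) and chp at 0.65 (1.46 to 1.61). On replicate 1, ple was at 1.14 (1.91 to 2.06), and on replicate 8, GstD10 was at 0.0051 (-0.98 to -0.92).

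Cytosolic ribosomal protein genes varied between arrays 2.53 times as much as the median gene. Replicate 7 alone is argued against as the whole source only by the bound of 1.2 set for it. Without that array the ratio was still 1.66 (bootstrap SD over genes 0.116). The bootstrap drew the 34 genes as if independent, but the estimated correlation within the list was 0.559. Its SDs are therefore likely too small, and the distance from the bound cannot be judged from them. A trend with brightness stays open: after the loess curve the ratio was 1.45, also above that bound, but its bootstrap SD of 0.273 reaches below it. That spread was not part of the bound as first written, under which 1.45 alone would have counted against the trend. No biological explanation was tested, since all arrays came from one homogenate.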

How the results depend on the processing

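The alternatives were set before the data were examined, except those with spots paired with a gene, the loess curve against brightness and the centring of genes on all spots, which were chosen after seeing the data. No value was missing, so other treatments of missing values change nothing and were not run. The cause was not tested for the changes below unless stated.

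The median residual SD of spots, 0.421, was 0.515 as deposited, 0.325 without the dimmest 25% of spots, 0.310 with spots paired with a gene and 0.276 after the loess curve, and ran from 0.344 to 0.439 with one replicate left out. That of genes, 0.301, was 0.454 as deposited and ran from 0.237 to 0.315. The 8491 spots past the threshold became 13696 with array weights and ran from 6133 to 13120, the highest without replicate 3. The 6077 genes ran from 5348 to 6278. The dye column, with 0 calls, gave 2113 spots and 1213 genes with array weights and 1 spot after the loess curve, and 0 with each replicate left out. Of the 28 lists, 11 passed camera, against 0 with an estimated correlation. With fry, which tests for no change and not against other genes, 18 passed, an answer to another question. Yp3 was reversed as deposited, at -0.41, where every ratio is lower because the median of all genes is -0.45. Signal over background was not used here, so its limit on dim spots is not known. Of the named genes, 125 kept their side and their call as deposited, 10 lost the call and 5 gained it, and 139 kept both under scaling and under quantile normalization, with 2 gained in each. Over all fits with one replicate left out, named genes lost a call 26 times and gained one 7 times, and lists lost 0 and gained 6.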

Other observations

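For the sides of the stage lists, the tests and the bootstrap over genes were chosen after the result was seen. The splits of the arrays and the test of dim spots were written before their results.

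The testis and sperm list had 18 members on the positive side, 4 on the negative and 9 not past the threshold, and the genes named here, apart from Prosalpha6T, were picked after their values were seen. The 4 on the negative side were Prosalpha6T at -2.15 ± 0.70 (SD, n = 8) and aly, can and comr at -0.47 ± 0.29, -0.38 ± 0.37 and -0.34 ± 0.38, the last 3 with limma adjusted p values of 0.00330, 0.0200 and 0.0408. Without replicate 3, can (adjusted p = 0.0593) and comr (0.0871) did not pass, and comr did not pass without replicate 4, 5, 6, 7 or 8 either (0.0517 to 0.117). On the positive side, Hsp60B was at 1.93 ± 0.56, dj at 1.66 ± 0.53, ProtB at 1.53 ± 0.39, ProtA at 1.28 ± 0.34, TrxT at 1.18 ± 0.45 and achi at 0.55 ± 0.19 (adjusted p = 0.000199, and 0.534 as deposited). The brightness of achi was low, at percentile 3.96 of genes. The 9 not past the threshold lay between -0.23 and 0.17, among them topi, twe and bol at 0.11 ± 0.28, 0.16 ± 0.40 and 0.17 ± 0.17, and topi passed without replicate 7 (adjusted p = 0.0489). No difference between subgroups of the list was tested.

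Of 34 larval cuticle and glue genes, 24 were on the negative and 8 on the positive side, and of 40 flight muscle and phototransduction genes, 20 were on the positive side, 2 on the negative and 18 not past the threshold. The median of the first minus that of the second was -1.35 ± 0.25 (SD over arrays, bootstrap SD over genes 0.264), negative on 8 of 8 arrays. The bootstrap drew genes as if independent, so its SD is likely too small. The list medians argue against positive ratios standing for larvae. However, Fbp1 (4.30), Cpr49Ah (3.92), Cpr49Ae (3.63) and TwdlT (2.80) of the larval lists were positive. For larval cuticle fry, which compares a list with no change, gave an adjusted p of 0.310. Which channel is the numerator stays unsettled. Mature adults of both sexes in one RNA were tested by a bound on the yolk, eggshell and accessory gland genes. It asked for a median over 1 in size, on the side of the flight muscle genes. The median was -0.26, and ran from -0.65 to -0.08 over the arrays. It was therefore under the bound and on the opposite side, which counts against the explanation by that bound. The explanation stays open all the same, since members went both ways (SD over genes 0.53). Yp1 at 1.17, EbpIII at 1.52 and the testis list's median of 0.77 were on the positive side, while the members named Acp ran from -0.59 to 0.50. Pupal material stays open too, since the excess of pupal and adult cuticle and ecdysone genes over those reproductive genes, 0.86 ± 0.33, restates list medians already seen and those lists are not of pupal genes alone. A mismatch of names and probes is argued against by 33 of 33 digestive genes on the negative side, where chance reaches 22.5.

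Of the dimmest 25% of spots, 960 passed the threshold, 958 of them on the positive side. Centred on their own median, 0.02% of the dimmest spots passed (1 spot), but that centring removes any shared offset whatever its source, so the source stays open.

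Of the 35 splits of the 8 arrays into 4 and 4, 1 split, the real one, gave 8491 spots and 6077 genes. The highest of the others was 0 for both. A share of 1 in 35 is the smallest that these splits can give. In the other splits the stage difference itself widens the residual spread, so their 0 does not measure false calls and does not exclude chance. Chance cannot be excluded for the count of lists either: 15 of the 35 splits gave as many as the real 11, and the highest other gave 17. Of these 15, 8 held 3 arrays of one orientation on a side and so kept part of the stage difference, and of the 18 splits that kept none of it, 6 gave as many, the highest 16.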
